A study of Mus musculus with 2 samples.

How the data were processed

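The series holds 2 libraries of Ago2 CLIP-seq, a method in which RNA crosslinked to Argonaute 2 by UV light is immunoprecipitated and sequenced. The cells were immortalised clonal lines of murine mesenchymal stem cells (MSCs) on the C57BL/6 background with floxed and undeleted Dicer. According to the labels, 1 line expressed human Ago2 with a Flag and HA tag and the other expressed it without a tag, the latter being the control of the immunoprecipitation. Doxycycline at 0.1 µg/ml, raised to 1 µg/ml after 24 h, induced the construct over 48 h. The lysate was treated with DNase and a limited amount of RNase I, and Ago2 was purified with both antibodies in tandem. Each group had 1 library, so no value has a replicate error.

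The analysis began from a single table of seed-match sites made by the authors, which lists sites of 30 miRNA families in isoforms above 0.1 FPKM. Its title calls them the top 30 miRNAs and gives no criterion. Per the submitters' processing notes, Bowtie and TopHat and the mouse builds mm9 and NCBIM37 were used, without versions or roles. The window in which reads were counted, the removal of duplicate reads and the way sites were searched are not given in the sources used here. The deposited CLIP value is RPM, a read count scaled to the size of the library, and the table has 1 such column. The file header does not tie this column to the tagged or the untagged library. Tagged and untagged signal were therefore not compared, no untagged background was subtracted, and every read count below may include background of the immunoprecipitation. The deposited FPKM of each isoform is the authors' value from RNA-seq of samples that are not stated. The deposited log2 coverage proved to be log2 of the RPM value minus a straight line in log2 FPKM with a slope of 0.347 and an intercept of 0.715, with a largest residual of 4.12e-11. The deposited conservation score is a phastCons fraction between 0 and 1, per the file headers, with no species set stated.

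All RPM values in the table were whole multiples of 0.211 RPM within a tolerance of 1e-06 reads, the value of 1 read in a library of 4735000 reads. Reads per site were recovered from this step for 100% of values. With a single column no count model could be fitted. Intervals of read counts are exact Poisson intervals, and intervals of shares are exact Clopper-Pearson intervals, both at 95%. They cover counting error only, since CLIP reads without known molecular identifiers are not independent molecules.

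The 412930 entries were collapsed to 385614 sites. A site was a family's match to the 6-nucleotide seed core at 1 genomic position and strand, taken in its longest form. A 7mer adds the base opposite miRNA position 8 and an 8mer adds an A after it. Gene, region and FPKM came from the entry with the highest FPKM. Families were named from general knowledge of miRNA seeds, since the table gives only the matched sequence. A site counted as supported at 1 or more reads. Positions are those of the mm9 build, 1-based.

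Each family, site type and transcript region was set against all others with a two-sided Fisher exact test and Benjamini-Hochberg adjustment at 0.05. Sites are not replicates, and neighbouring sites share reads. The correlation of log2 reads across pairs of sites was 0.998 at 1 to 2 nt and 0.716 at 41 to 60 nt. It was still 0.645 at 81 to 120 nt, so correlation at the longer distances need not come from shared reads. The p-values are thus too small and describe this table only. Odds ratios carry a 95% interval from 1000 bootstrap draws of whole genes. In addition, Mantel-Haenszel odds ratios were computed over region and 10 classes of FPKM. For 10 gene lists, the share of genes with a supported site was compared with all other genes by Fisher's exact test. The median of log2(reads per group of sites + 1) was also placed among 10000 random lists matched on FPKM (10 classes) and number of site groups (3 classes), with sites within 40 nt of each other chained into groups and the highest count taken from each. The smallest p these random lists can give is 0.0002. Analyses ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and plots in matplotlib 3.10.9.

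The groups, the Fisher tests, the gene lists, the 1-read threshold and most alternatives were set before the data were examined. A first look at the table, which showed family odds ratios, shares by type and region and list percentiles, preceded the remaining choices. These were the collapsing of nested matches, the choice of region by highest FPKM, the 40-nt groups, the gene score, the matching classes, the Mantel-Haenszel fit, the bootstrap, the 10-read view of 8mers against 6mers, the conservation threshold of 0.9 and the set of 100 top groups. Named genes followed a rule set beforehand. It took Nr6a1, Hmga2 and up to 12 let-7 list genes with most reads, the 10 genes with most reads over all families, the 3 top genes of each of the 5 families with most supported sites, and the 3 top genes of each other list. Its part on untagged signal had no column to act on. Genes outside this rule are named as such. Some results for single genes are not reported here.

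The procedures were tested on simulated data. Of 6 families given an odds ratio of 1.3 among the 385614 sites, the Fisher test and the Mantel-Haenszel fit each recovered 6. Of 24 unchanged families the Fisher test also called 4, because families differ in the expression of their genes and simulated support was made to depend on FPKM, and the Mantel-Haenszel fit, here over FPKM classes alone, called 0. Simulated support was drawn independently for each site and without an effect of region, whereas real neighbouring sites share reads. These calls therefore do not measure error rates on the real table. Matched lists of 20 genes raised by 1.5 on the log2 scale were recovered in 40 of 40 cases, and 5 of 40 unraised lists were called. Alternatives covered 3 or 10 reads for support, all entries counted, 3′ UTR sites alone, genes at 1 or 10 FPKM, overlapping sites merged or left out, nested matches kept apart, and noncoding transcripts left out.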

Results

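The table described Ago2 CLIP reads at 385614 seed-match sites of 30 miRNA families in murine mesenchymal stem cells. Of these sites, 167434 carried at least 1 read, a share of 43.4% (95% exact interval 43.3 to 43.6). Signal was thin at most of them: supported sites had a median of 3 reads, 29.8% had a single read, and 30072 sites (7.80%) reached 10 reads. At least 1 supported site was found in 10853 of 14193 gene or transcript names (76.5%). The design sets a tagged against an untagged line to separate Ago2-bound RNA from background, but the read column could not be assigned to either line. That comparison was not made, and the overall share depended on the setting, from 7.80% at 10 reads to 71.3% in genes at 10 FPKM or more.

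The largest read counts lay on a short list of transcripts. The highest was 13906 reads (95% Poisson interval 13676 to 14139) at a 7mer for miR-34 in the pseudogene 9930038K12Rik, at chromosome 6, 52180096 to 52180102. The lncRNAs ENSMUST00000152278 and ENSMUST00000152279 had single sites of 6323 and 3946 reads at isoform levels of 0.37 and 0.44 FPKM. Dvl2, which encodes a Dishevelled protein of Wnt signalling, had 3215 reads at a miR-34 7mer in its 3′ UTR. Cherp had 5994 reads over its site groups, of which 4498 lay at a miR-143 6mer in the coding sequence at chromosome 8, 74993990 to 74993995. Among the other genes with most reads were Col1a2 (4469 reads over its site groups), the growth factor gene Csf1 (4012 reads), linc444 (3294 reads), the fatty acid desaturase gene Scd2 (3167 reads) and Col1a1 (2667 reads).

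Sites of let-7 carried reads more often than those of any other family. Of 8137 let-7 sites, 55.5% were supported, against 43.2% of the sites of all other families, an odds ratio of 1.64 (95% gene bootstrap interval 1.56 to 1.73). Other high families were miR-103/miR-107 with an odds ratio of 1.42 (1.36 to 1.47), miR-30 with 1.36 (1.29 to 1.44), miR-15/miR-16 with 1.32 (1.27 to 1.36), and miR-130/miR-301 and miR-19 with 1.28 each. Low families were miR-145 (0.79, interval 0.76 to 0.82), miR-199-5p and miR-140-3p, all at 0.79. Apart from let-7, the order rested on the setting: miR-30 was second in 3′ UTRs (1.44) and at 10 or more reads (1.92) and miR-196 in the Mantel-Haenszel fit over region and FPKM (1.45), while the lowest was miR-199-5p in that fit (0.73) and miR-423-3p at 10 or more reads (0.37). Sites of miR-21 (43.9%) and miR-26 (43.4%) did not pass the test, with odds ratios of 1.02 (0.97 to 1.07) and 1.00 (0.96 to 1.04), though miR-21 passed it at 3 or more reads, in genes at 1 and 10 FPKM or more, without overlapping sites and without noncoding transcripts (1.07 to 1.17), and miR-26 was lower in the Mantel-Haenszel fit (0.94). In the Fisher exact test with Benjamini-Hochberg adjustment, 11 families were higher and 15 lower, with an adjusted p of 5.7e-107 for let-7, and the Mantel-Haenszel fit called 11 higher and 17 lower. At 10 or more reads the let-7 odds ratio was 3.06.

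Some of the miR-103/miR-107 and miR-196 sites share bases with seed matches of miR-15/miR-16 and let-7. In 3′ UTRs, miR-196 sites that overlapped a let-7 site were supported in 73.0% of 1253 cases, and those that did not in 58.2% of 3185. For miR-103/miR-107, the shares were 69.0% of 4281 sites overlapping miR-15/miR-16 matches and 61.2% of 4455 others.

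The 5 families with the most supported sites were miR-15/miR-16, miR-103/miR-107, miR-186, miR-27 and miR-22. They also had the most listed sites, from 20062 to 27894. Shares with reads were above the 43.4% of all sites for miR-103/miR-107 (51.6%) and miR-15/miR-16 (49.8%). They were below it for miR-186 (39.2%), miR-22 (41.5%) and miR-27 (42.9%, not past the threshold). The transcripts with most reads at sites of both miR-15/miR-16 and miR-103/miR-107 were ENSMUST00000152279, Dvl2 and linc444. In each, the top sites of both families overlapped, so these reads were counted for both. The shared counts were 3473 reads in ENSMUST00000152279 and 3209 in Dvl2, where miRNA hairpins are considered below as a candidate source. At miR-27 sites the top genes were Scd2 with 1665 reads, Csf1 with 1069 and Tmbim6 with 667. The Scd2 reads lay mostly at a 7mer in its 3′ UTR, at chromosome 19, 44380935 to 44380941, with 1619 reads. For miR-186 they were linc444 with 1273 reads, Rbms1 with 1088 and Zfp275 with 412. For miR-22, Ptms had 1024 reads and the histone gene H2afx had 989, with their top sites in 5′ UTRs, and Eif4h had 435.

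Support rose with the length of the seed match. Over all regions, 50.8% of 8mers, 46.4% of 7mers and 41.9% of 6mers carried reads, with odds ratios against the other types of 1.38 (1.34 to 1.42), 1.17 (1.15 to 1.19) and 0.79 (0.78 to 0.81). In 3′ UTRs the shares were 65.4%, 61.1% and 56.0%. The gap widened with signal, since 23.1% of 3′ UTR 8mers but 11.5% of 6mers had 10 or more reads, and over all regions the 8mer odds ratio at that threshold was 2.16.

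**Figure D1:**
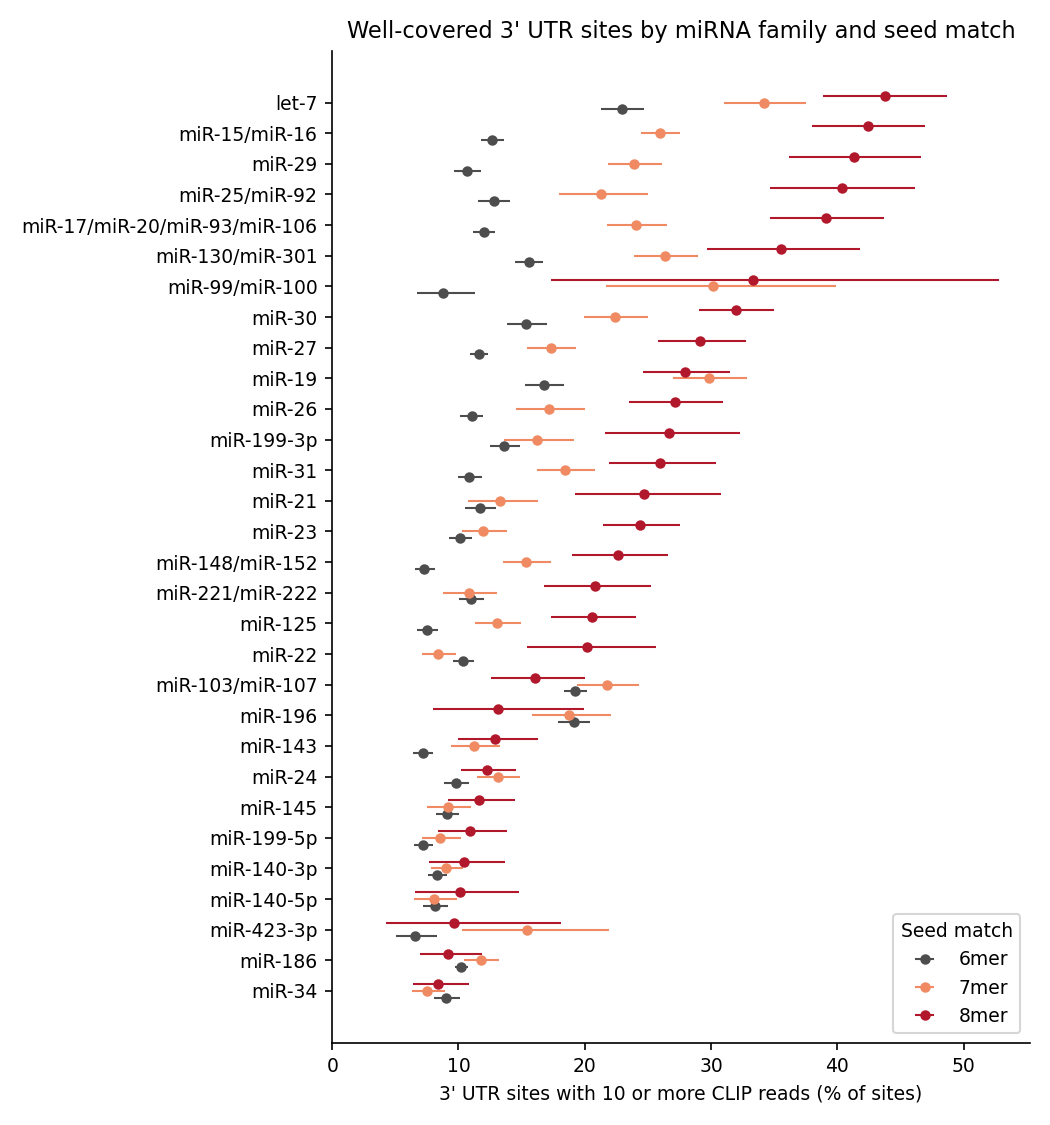
Share of 3′ UTR sites with 10 or more CLIP reads (x axis, percent of sites) for 30 miRNA families (y axis) and 3 seed-match types, with 95% exact binomial intervals. The 8mers of let-7, miR-15/miR-16 and miR-29 lie at 43.8%, 42.4% and 41.3%, while miR-34 and miR-186 8mers lie at 8.41% and 9.20%, near their 6mers.

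The preference for 8mers differed in size between families. For miR-29, 41.3% of 3′ UTR 8mers and 10.7% of 6mers had 10 or more reads. The corresponding shares were 42.4% and 12.7% for miR-15/miR-16 and 43.8% and 23.0% for let-7, and miR-17/miR-20/miR-93/miR-106 had 39.1% for 8mers and an odds ratio of 4.71 over its 6mers. At miR-196, miR-103/miR-107, miR-34 and miR-186 sites, 8mers were not higher than 6mers at this threshold, with odds ratios of 0.64, 0.80, 0.92 and 0.89. For the first 2 the direction turned at sites away from let-7 and miR-15/miR-16 matches, where 13.5% of miR-196 8mers and 11.9% of 6mers, and 16.0% of miR-103/miR-107 8mers and 12.8% of 6mers, had 10 or more reads, neither difference past the threshold (Fisher exact p = 0.583 and 0.0716). With support at 1 read, 8mers exceeded 6mers in 20 of 30 families in the adjusted Fisher exact test. That number fell to 12 in genes at 10 FPKM or more and to 13 at sites overlapped by no other site.

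By region, 3′ UTR sites carried reads most often and sites in lncRNAs and pseudogenes least. In 3′ UTRs 57.7% of 175561 sites were supported, an odds ratio of 2.98 against all other regions (2.70 to 3.36). The share was 47.4% in coding sequence, 33.6% in 5′ UTRs, 6.67% in pseudogenes and 2.97% in lncRNAs. The order of the last 2 turned within FPKM classes, with odds ratios of 0.0743 for pseudogenes and 0.0849 for lncRNAs. The odds ratio of 5′ UTR sites was 0.64 (0.59 to 0.70). That of coding sites was 1.26 (1.14 to 1.40) against all other regions pooled, but 0.99 within classes of FPKM, where it did not pass the threshold, and 0.51 at 10 or more reads, so its direction rested on the setting. The 3′ UTR odds ratio stayed above 1 and ranged from 1.69 without noncoding transcripts to 4.86 at 10 or more reads.

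**Figure D2:**
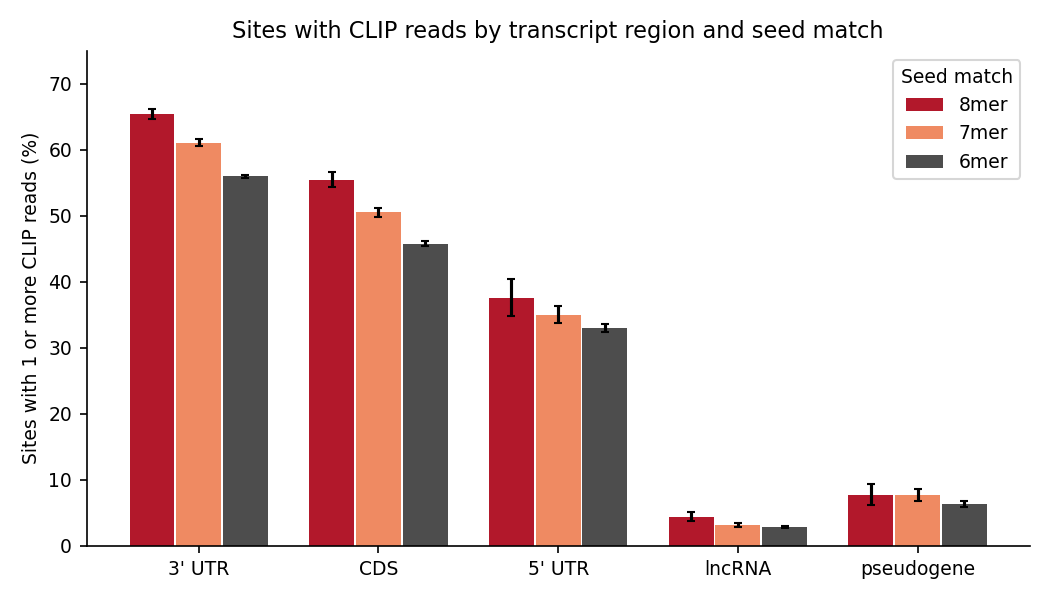
Share of sites with 1 or more CLIP reads (y axis, percent) by transcript region (x axis) and seed-match type, with 95% exact binomial intervals. In 3′ UTRs the bars stand at 65.4% for 8mers, 61.1% for 7mers and 56.0% for 6mers, and in lncRNAs at 4.37%, 3.14% and 2.80%.

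The let-7 comparison asked whether known let-7 targets, among them Nr6a1, carried Ago2 reads at their let-7 sites. Nr6a1, an orphan nuclear receptor and the gene named in the series title, had 8 let-7 sites in its 3′ UTR, and all 8 carried reads, 107 over their groups, although the transcript was listed at only 0.75 FPKM. Its highest count was 33 reads (23 to 46) at the 8mer CTACCTCA on chromosome 2, 38579205 to 38579212, on the minus strand. A 7mer beside it, at 38579196 to 38579202, had 29 reads, and another at 38579031 to 38579037 had 26. The 2 adjacent counts are not independent, since a read can span both. Counting sites of all families, 74 of the 82 sites of Nr6a1 had reads, with 416 reads over their groups. Frequent support in this gene was thus not particular to let-7.

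Hmga2, a chromatin architectural factor and a classical let-7 target, had 6 of 9 let-7 sites with reads and 128 reads over their groups. Of these, 97 (79 to 118) lay at a 3′ UTR 7mer at chromosome 10, 119800044 to 119800050. The 8mer in its 3′ UTR, at 119801280 to 119801287, had 0 reads, with an upper Poisson bound of 3.69. With sites of all families counted, 41 of the 51 Hmga2 sites had reads, with 278 reads over their groups. Support in Hmga2 was thus not particular to let-7 either.

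**Figure D3:**
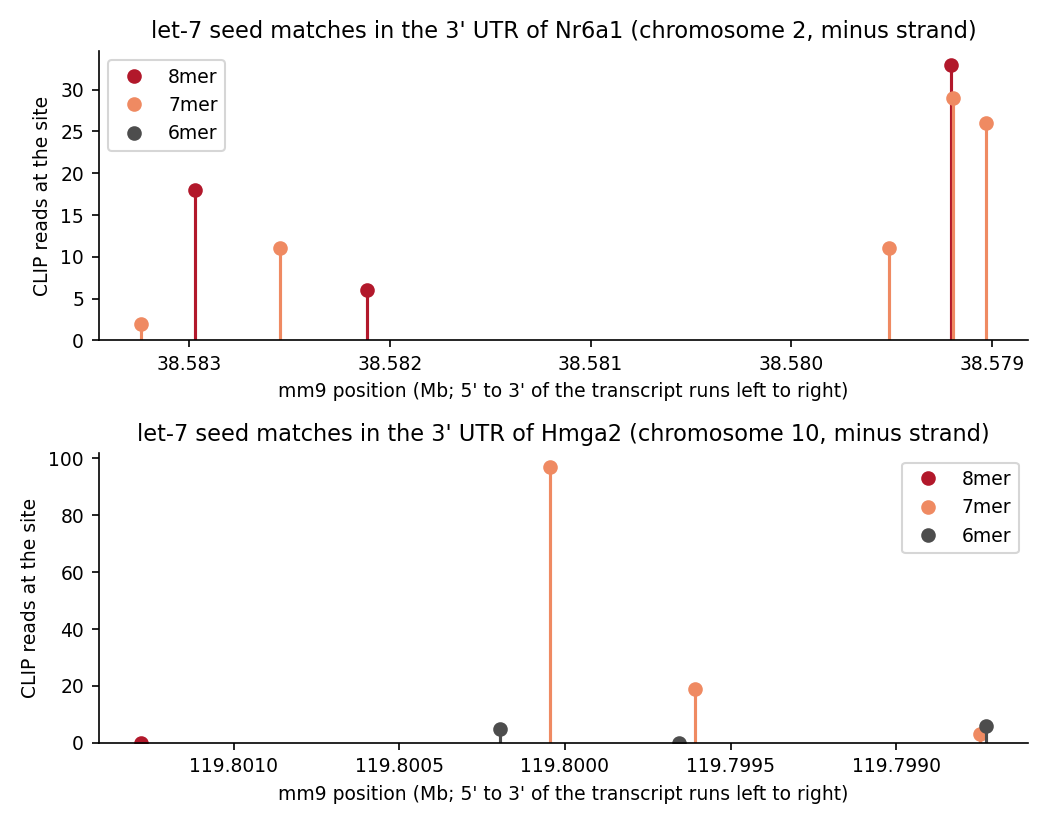
CLIP reads (y axis) at each let-7 seed match in the 3′ UTRs of Nr6a1 (top) and Hmga2 (bottom) by mm9 position (x axis, Mb, drawn in transcript direction). Each stem is 1 site, coloured by seed-match type. Nr6a1 has 8 sites with reads and a highest count of 33, and Hmga2 has a highest count of 97 and an 8mer at 0.

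Of the other let-7 list genes, Thbs1, Slc20a1, Nras and Tgfbr1 had more reads at let-7 sites than Hmga2, and the rest had fewer than Nr6a1. Thbs1, which encodes thrombospondin, had 714 reads (663 to 768) at a 3′ UTR 6mer on chromosome 2, 117952275 to 117952280, in a transcript of 335 FPKM. The phosphate transporter gene Slc20a1 had 249 reads, with 183 at a 5′ UTR 6mer, and the Ras gene Nras had 214, with 186 at a 3′ UTR 7mer on chromosome 3, 102868297 to 102868303. Tgfbr1, a TGF-β receptor, had 146 reads, Smarcad1 had 105, and the E2F factors E2f5 and E2f6 had 86 and 82. Arid3a had 78, Myc 53 (at a coding 6mer) and Plagl2 47.

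**Figure D4:**
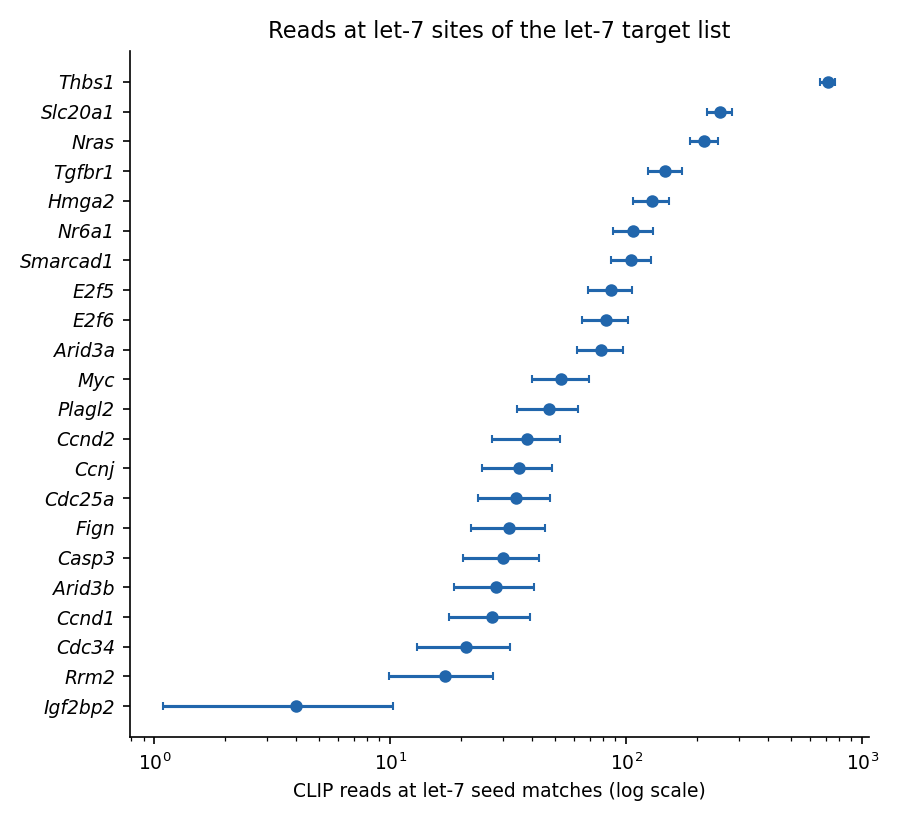
CLIP reads at let-7 sites (x axis, log scale) for the 22 let-7 list genes with a let-7 site (y axis), summed over site groups, with 95% exact Poisson intervals. Values run from 4 reads for Igf2bp2 to 714 for Thbs1.

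Across the list, 54 of 58 let-7 sites carried reads (93.1%, interval 83.3 to 98.1), against 55.2% of let-7 sites in other genes (Fisher exact p = 3.0e-10 over sites). By gene, 22 of 22 list genes with a let-7 site had reads there, against 66.8% of 4801 other genes (Fisher exact p = 0.000301). Their median was 2.92 higher on the log2 scale than that of matched random lists, above all 10000 of them. The 22 genes also had reads at 83.2% of their sites of other families away from let-7 sites, against 40.1% in other genes with a let-7 site. In genes at 10 FPKM or more the share difference shrank from 37.9 to 13.2 points and no longer passed the test. The genes Acvr1c, Igf1r, Igf2bp1, Igf2bp3, Lin28a, Lin28b, Mycn and Trim71 were not analysed here.

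Genes of the miR-29 list carried reads over many sites of that miRNA. Of 122 miR-29 sites in 18 of its genes, 112 had reads (91.8%, against 46.2% in other genes). The 18 genes include Dnmt3a, Tet2 and Mcl1, which do not encode matrix proteins. Col1a2, Col1a1, Col5a2 and Col5a1 held 22, 22, 18 and 12 of the sites, so the share largely describes these collagen genes. Of the genes just named, all but Col1a2 and Col1a1 lie outside the naming rule. The fibrillar collagen genes Col1a2 and Col1a1 each had reads at all 22 of their miR-29 sites, 1732 and 1574 reads over the groups. Over all 30 families, however, 75 of 77 and 73 of 73 of their sites had reads, so full support was not particular to miR-29. Most of these sites lay in coding sequence, 63 of 77 in Col1a2 and 49 of 73 in Col1a1. Col1a2 had 12 sites of all families in its 3′ UTR, so its 22 miR-29 sites were not all 3′ UTR matches. The matricellular gene Sparc had 475 reads at 2 miR-29 sites. Adamts9, in contrast, had 0 reads at 2 sites. The miR-17/miR-20/miR-93/miR-106 list had reads at 29 of 37 sites of its family (78.4% against 44.9%), led by Tgfbr2 with 189 reads. Over all families Tgfbr2 had 330 reads, with 187 at a miR-19 7mer. At least some of the 189 were therefore counted in the same site group as the miR-19 site. The miR-21 list had reads at 9 of 10 sites (90.0% against 43.8%), led by the inhibitory Smad gene Smad7 with 75. Much of each excess was not particular to the family, since the same genes had reads at 66.7% (miR-29 list), 66.9% (miR-17/miR-20/miR-93/miR-106 list) and 67.7% (miR-21 list) of their sites of other families away from these, against 41.9%, 41.9% and 39.8% in other genes with a site of the family.

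Over sites of all 30 families, 8 of the 10 gene lists lay above matched random lists after adjustment, with medians of reads per group raised by 2.04 (let-7 targets), 1.83 (miR-29 matrix targets), 1.74 (cell cycle), 1.47 (mesenchymal markers), 1.37 (miR-21 targets), 1.15 (TGF-β and BMP signalling), 1.07 (miR-17/miR-20/miR-93/miR-106 targets) and 0.90 (miRNA machinery) on the log2 scale. Abundant housekeeping genes were 0.58 above (adjusted p = 0.201) and markers of other cell types 0.06 below (adjusted p = 0.841, a permutation of list membership), neither past the threshold. Of the marker genes of other cell types, 4 of 8 in the table had a supported site, led by Runx2 with 144 reads, Cd34 with 22 and Sox9 with 21. In genes at 10 FPKM or more 4 lists were above random lists, and the miR-17/miR-20/miR-93/miR-106, miR-21, TGF-β and BMP and miRNA machinery lists no longer passed. The miRNA machinery list also did not pass in 3′ UTR sites alone (0.49) or in genes at 1 FPKM or more (0.73).

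In the cell cycle list, the CDK inhibitor gene Cdkn1b had 1016 reads, with 330 at a miR-24 8mer, the cyclin gene Ccna2 had 671, with 275 at a let-7 8mer, and Cdk2 had 453. In the TGF-β and BMP list, Tgfbr3 had 875 reads, with 362 at a let-7 8mer, Smad7 had 862, with 636 at a miR-15/miR-16 8mer, and Ski had 509. The top mesenchymal genes were Col1a2, Col1a1 and Vim (vimentin, 963 reads). Among miRNA machinery genes, Tnrc6b had 946 reads, Eif2c2, which encodes Ago2 and whose human form the lines expressed, had 813, and Tnrc6a had 715. Of the other 2 miRNA target lists, Vegfa (1163), Ccnd1 (360) and Tgfbr2 (330) led the miR-17/miR-20/miR-93/miR-106 list, and Smad7, Btg2 (526) and Tgfbr2 led the miR-21 list. Housekeeping genes with most reads were Actb (849), Hsp90ab1 (607) and Tubb5 (480).

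By share of genes with at least 1 supported site, the let-7 (24 of 24), TGF-β and BMP (20 of 20), cell cycle (19 of 19) and housekeeping (17 of 17) lists exceeded the 76.4% of other genes, with Fisher exact adjusted p of 0.0273, 0.035, 0.039 and 0.0464 over the 10 lists. None of these 4 excesses passed in 3′ UTR sites alone or in genes at 1 FPKM or more, and the housekeeping difference turned to -1.91 points in 3′ UTR sites. This measure saturates, since lists at 100% cannot be ranked.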

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

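Nested matches kept apart, the Mantel-Haenszel fit, the removal of noncoding transcripts, the 8mer test away from shared matches and the lists at sites of other families were chosen after seeing the data, and the other alternatives beforehand. The share of sites with reads moved with each setting: 23.2% at 3 reads, 7.80% at 10 reads, 44.1% over all entries, 57.7% in 3′ UTRs, 55.9% and 71.3% in genes at 1 and 10 FPKM, 42.8% with overlapping sites merged, 42.1% without overlapping sites, 43.9% with nested matches kept and 51.9% without noncoding transcripts. In genes at 10 FPKM, where fewer genes were tested, families with higher 8mers fell to 12, lists above random lists to 4 and the let-7 list share difference to 13.2 points. Without overlapping sites, families with higher 8mers fell to 13; the cause was not tested. The coding-sequence odds ratio reversed to 0.783 at 3 reads, 0.513 at 10 reads, 0.961 and 0.848 in genes at 1 and 10 FPKM, 0.993 in the Mantel-Haenszel fit and 0.756 without noncoding transcripts. The housekeeping share difference reversed to -1.91 points in 3′ UTRs. The cause of these reversals was not tested. The odds ratios of let-7, 8mers and 3′ UTR sites kept their direction and side of the threshold in every alternative that applied (30 values). For the let-7 list, differences in its median over all sites and in share and median at let-7 sites were also followed. Of these, 23 kept both too, and 1 kept its direction but lost the threshold. That was the share difference at let-7 sites in genes at 10 FPKM or more. These values do not cover the other families. Counts of calls have neither and moved, from 11 to between 11 and 13 for families higher, from 15 to between 12 and 17 for families lower, from 20 to between 17 and 22 for families with higher 8mers otherwise, and from 8 to 7 or 8 for lists otherwise, and equal counts can hold different families or lists. The remaining values were those of site types, regions, lists and only some of the other families. Among them, 164 odds ratios and 135 differences kept both. A further 2 of each turned without passing the threshold in either setting, 24 values lost the threshold and 15 gained it. Families left out do not enter these numbers. Of those, miR-199-3p lost the threshold at 10 reads and miR-31 in 3′ UTRs, whereas miR-24 kept it in both settings. The thresholds of 3 and 10 reads do not enter the list medians. Alternatives based on untagged signal were not run, as no column could be assigned to it. No paired analysis was possible because each group had 1 library and there was 1 CLIP column. Depth limits single sites, as 29.8% of supported sites rest on 1 read.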

Other observations

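All of the patterns here were noticed in the data. The tests of gene length, of precursor spacing and of 8mers away from shared matches were chosen after the results were seen, and the conservation contrast has no planned counterpart. A test of whether expression accounts for that contrast was also run, and its value is the odds ratio within FPKM classes below. No biological explanation was tested for any pattern, as the groups of the design were not resolved.

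Conserved 3′ UTR sites carried reads more often than other 3′ UTR sites. At a phastCons score of 0.9 or more, 75.2% of 37747 sites had reads, against 52.9% of 137814 others, an odds ratio of 2.70, and of 2.78 within FPKM classes (95% gene bootstrap interval 2.63 to 2.94). The odds ratio within FPKM classes was 3.51 for 8mers (3.17 to 3.88), 2.78 for 7mers (2.57 to 3.01) and 2.60 for 6mers (2.45 to 2.75). The 2 neighbouring Nr6a1 sites with most reads had scores of 0.0042 and 0.0003, and the Hmga2 7mer with 97 reads had a score of 1.

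Some 5′ UTRs held very high counts at a single listed site, named here after their values were seen. Mphosph10 had 1248 reads at a 6mer for miR-221/miR-222 on chromosome 7, 71537082 to 71537087, and Grcc10 had 1189 at a 6mer for miR-199-5p on chromosome 6, 124691229 to 124691234. In coding sequence, the ferritin heavy chain gene Fth1 had 1009 reads at a miR-23 6mer and the chaperonin gene Tcp1 had 940 at a miR-103/miR-107 7mer. In 3′ UTRs, the heterochromatin protein gene Cbx5 had 2596 reads, 769 of them at a let-7 7mer.

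Families miR-196 and miR-103/miR-107 had odds ratios above 1 although their 8mers did not exceed their 6mers at 10 or more reads over all 3′ UTR sites. Reads counted at an overlapping match of another family are a candidate explanation. For miR-196, the 3′ UTR odds ratio was 1.22 over all sites and 1.03 (0.952 to 1.095) at sites overlapping no let-7 match, so no excess beyond the error was seen once shared positions were removed. For miR-103/miR-107 it fell from 1.38 to 1.17 (1.105 to 1.243) away from miR-15/miR-16 matches, between the bounds set beforehand, so sharing may account for part and the rest stays open. Away from shared sites 8mers were higher for miR-196 (odds ratio 1.16, 133 8mers) and miR-103/miR-107 (1.31, 399 8mers, none of which overlapped a miR-15/miR-16 match). Leaving out shared sites took away far more 6mers than 8mers, from 3678 to 2632 for miR-196 and from 7230 to 3542 for miR-103/miR-107. Neither difference passed the Fisher exact test away from shared sites (p = 0.583 and 0.0716) or over all sites (p = 0.0947 and 0.116). Whether these 8mers are preferred stays open.

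The 100 site groups with most reads for their expression included 9930038K12Rik, both unnamed lncRNAs and Dvl2, and reads of miRNA hairpins, themselves bound by Ago2, are a candidate source. Of the 92 groups in genes matched to the GRCm38.p6 gene table, 15.2% (8.58 to 24.2) lay in a gene with a miRNA gene inside it or within 2 kb, against 7.05% of all groups with reads in matched genes, an excess only narrowly past the preset bound. Groups with reads in genes of like length gave 6.97%, under the lower end of that interval. The interval treats groups as independent, though genes such as Cherp recur among them. It is thus too narrow, and longer host genes are not excluded as an account. The median of 3.43 FPKM, against 8.68 over all groups with reads, decides nothing about transcript abundance, as the ranking itself was relative to expression. In 3 of the 4 transcripts named, 9 of 9 seed matches of a miRNA precursor were listed at their spacing in the precursor, but the precursor sequences came from general knowledge and were picked because they matched, a precursor tried first for ENSMUST00000152278 having failed, so this too decides nothing. Hairpin reads thus may explain some of these counts, and for most of the 92 groups the gene table gave no miRNA gene nearby. It gave none for the 4 transcripts named either, Dvl2 among them, although precursor matches were listed there. The lookup can therefore miss hairpins, and the 15.2% may be too low.

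The let-7 list exceeded matched lists at let-7 sites, which could reflect genes rich in CLIP reads at sites of every family. At their sites of other families, away from let-7 sites, the 22 genes exceeded matched lists by 1.40 on the log2 scale, against 2.89 at let-7 sites (2.92 in the report, where random lists were not limited to genes with both kinds of site), so a general excess was present. With this matching, the general excess was not the whole of the pattern. The median gene-wise difference between both kinds of site was 1.66, against 0.27 in matched lists, 1.39 above them (percentile 99.91). Of the 22 genes, 20 were higher at let-7 sites, a count given without a counterpart from matched lists. The excess at other sites lay only just under the preset bound of 1.44, which is 50% of the 2.89. Matching did not include site type, transcript region or conservation, so a difference in region between both kinds of site was not removed. A let-7-specific part therefore remains a hypothesis, with background of the immunoprecipitation untested.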
